A study of Homo sapiens with 16 samples.

How the data were processed

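RNA from H9 cells, an established human embryonic stem cell line, was measured on 16 Human Exon 1.0 ST arrays. Per the labels, the arrays cover undifferentiated cells (day 0) and cells after 1, 3 and 5 days with activin A at 100 ng/ml. Total RNA was depleted of ribosomal RNA, amplified as cDNA, biotinylated and hybridised. The labels number 4 biological replicates at day 0, 3 at day 1, 3 at day 3 and 4 at day 5. Biological replicate 4 of day 0 and of day 5 was hybridised on a pair of arrays that the labels call technical replicates.

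The deposited values are gene-level intensity on a linear scale, and the authors' processing notes name the genome build hg18. The tools used for summarisation, background correction and normalization are not given in the sources used here. The deposited table held 18495 probe sets with values from -0.273 to 30307.1, and 636 values were below 0. The array medians ran from 245.1 to 246.3 and every value was a whole multiple of 1/22 (tolerance 0.001 after multiplication by 22), so the arrays look quantile normalized, which was inferred from the values alone. An array has no read depth, and the number of arrays limits the precision here.

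Values were taken to log2 after adding 1, and technical replicates were averaged with avearrays, which left 14 biological samples. Probe sets were named by symbol. 14577 carried 1 symbol, 2849 carried several and 1069 carried none. The latter groups stayed in all tests and were never named, which leaves out POU5F1, NANOG, SOX2, LEFTY1 and LEFTY2, because their probe sets carry several symbols.

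Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with group as the only term, and p-values were adjusted with the Benjamini-Hochberg method over the 18495 probe sets at a threshold of 0.05. The fit had 10 residual degrees of freedom and 3 prior degrees of freedom. A moderated F test covered the 3 contrasts with day 0. Counts of genes past a test over all probe sets are counts of probe sets, including those with several symbols or none. Transient genes had to be at least 2-fold higher at day 1 than at day 0 and at least 2-fold lower at day 5 than at day 1, each past the threshold. Changes are log2 ratios ± standard error (SE) from limma, and group means are log2 intensities ± standard deviation (SD).

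There were 34 gene lists with 738 genes, written from textbook knowledge. Of these genes 609 had a probe set of their own, 70 were only on probe sets with several symbols and 59 had none. Some genes are in several lists, so list counts and calls are not independent. The primitive streak list, for instance, shares members with the FGF, nodal and WNT signalling lists. For a gene with several probe sets the one with the highest mean was used. Lists were tested with camera of limma at a preset correlation of 0.01, with the estimated correlation and fry as alternatives, adjusted over 170 tests (34 lists in 5 contrasts). The number of members past the test is given over all probe sets and adjusted over the list alone.

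The named genes followed a rule. It takes 12 fixed markers in the contrasts with day 0, of which 9 had a probe set of their own. It adds, per contrast, the 6 highest and 6 lowest changes past the test among genes whose groups do not overlap, and per list up to 3 members with the largest change past the test, or the 2 largest where none passed. From the last part the text gives a selection. Genes on probe sets with several symbols or none are never named. Genes named outside the rule are said to have been chosen after their values were seen. The groups, comparisons, lists, naming rule and most alternatives were fixed before the data were examined.

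The alternatives were: all 16 arrays with the sample as a random block, either technical replicate alone, the replicate number as a block, a fit of only the groups compared, quantile normalization, median centring, leaving out the dimmest 25% of probe sets, a variance trend with robust eBayes, array weights, stricter thresholds, 1 probe set per gene, a pseudocount of 16, and leaving out each biological sample in turn. Leaving out day 3 replicate 2 in contrasts that do not use it, and leaving out day 3 and day 5 replicate 2 together, were added after seeing the data.

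The limma and camera code was tested on simulated data with known changes. On the spread of these samples, simulated changes of 2 on the log2 scale were called for 58% of 50 genes at day 1, 74% at day 3 and 66% at day 5. Simulated changes of 4 were called for 98%, 98% and 100%. Of the unchanged probe sets 6, 18 and 11 were called. The changed genes were drawn at random among brighter genes and given independent noise. These shares need not hold for genes whose spread day 3 replicate 2 widened. Gene spans for the length test came from RefSeq on GRCh38. Figures and tables used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.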

Results

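The study followed H9 human embryonic stem cells through a directed differentiation toward endoderm, the germ layer of gut, liver and pancreas. Expression was measured on exon arrays in 4 biological samples of undifferentiated cells, 3 after 1 day with activin A, 3 after 3 days and 4 after 5 days. Activin A is a ligand of the nodal pathway and was given at 100 ng/ml in RPMI while serum was raised from 0% to 0.2% and 2%. Undifferentiated cells grew in feeder-conditioned medium with basic FGF at 8 ng/ml, so activin, medium and serum all changed together with time and their effects cannot be separated. The array medians lay between 245.1 and 246.3 intensity units. The first principal component (45.9% of the variance) was led by replicate 2 of days 3, 5 and 1 (scores 0.597, 0.502 and 0.243), and on the second (24.9%) days 0 and 1 overlapped, with scores of -0.31 to -0.215 and -0.238 to -0.15. Day 5 scored 0.276 to 0.457 there. Day 3 replicates 1 and 3 scored 0.168 and 0.221, and day 3 replicate 2 scored -0.129, close to day 1. The library labelled day 3 replicate 2 stood apart, with a median correlation of 0.829 with the other day 3 samples, and day 5 replicate 2 had 0.858 with its group, against 0.901 to 0.962 for the others. Both were kept in every comparison, and values without day 3 replicate 2 are given beside the genes and lists named in a comparison where it changes their call.

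Day 1 was compared with day 0 to ask which genes respond first to activin. MIXL1, a homeobox gene of the primitive streak, had a mean log2 intensity of 12.50 ± 0.89 (SD, n = 3) at day 1 and 7.16 ± 0.56 (n = 4) at day 0, a difference of 5.34 ± 0.95 (SE) with an adjusted p of 0.0882. EOMES, a T-box factor needed for endoderm, differed by 5.59 ± 1.11 (adjusted p 0.107), and the organizer gene GSC by 5.26 ± 1.09 (adjusted p 0.121). All 3 day 1 samples lay above all 4 day 0 samples for each of these 3 genes. Over all probe sets, 2123 (11.5%) had groups that did not overlap in either direction at day 1, where chance separates 5.71%. With day 3 replicate 2 left out, which enters only through the shared estimate of spread, the adjusted p fell to 0.000812 for MIXL1, 0.000336 for EOMES and 0.000613 for GSC. The mesoderm gene TBXT differed by 1.55 ± 0.58 (adjusted p 0.638) and the endoderm gene SOX17 by 0.95 ± 1.08 (adjusted p 1). FOXA2 differed by 1.22, CXCR4 by 0.78, CER1 by 1.75 and GATA6 by 2.59, none past the test.

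At day 1 the only gene past the test was SLC24A2, a sodium, potassium and calcium exchanger, which fell by 2.23 ± 0.27 (adjusted p 0.0327). It lost that call without any 1 of the 7 samples compared, with adjusted p values from 0.0692 without day 1 replicate 3 and 0.0751 without day 1 replicate 2 to 0.17 without day 1 replicate 1, and 0.145, 0.198, 0.118 and 0.165 without day 0 replicates 1, 2, 3 and 4. SLC24A2 had a low mean at day 1 (4.99, against 7.22 at day 0), so the size of its fall depends on the pseudocount. It was itself among the dimmest probe sets, so it was not tested when those were left out, where 12 genes were called. It was called with a pseudocount of 16. The count with all samples was 1 gene (0 higher, 1 lower). It was 0 without each of those 7 samples and 46 without day 3 replicate 2, and 1116 probe sets had an unadjusted p under 0.05.

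At day 1 FGF4, a growth factor of stem cells and the streak, differed by 3.54 ± 0.50 (adjusted p 0.0649, and 0.0194 without day 3 replicate 2). The WNT antagonists DKK4 and DKK1 differed by 5.17 ± 0.97 (adjusted p 0.107) and 4.33 ± 0.90 (adjusted p 0.121, and 0.0085 without day 3 replicate 2). The nodal pathway ligands GDF3 and NODAL differed by 2.15 ± 0.39 (adjusted p 0.0907, and 0.0465 without day 3 replicate 2) and 1.38 ± 0.27 (adjusted p 0.107). The tight junction gene CLDN4 differed by -1.38 ± 0.27 (adjusted p 0.107).

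As a group, the primitive streak list was higher at day 1 (camera adjusted p = 1.18e-15, and 0.0716 with an estimated correlation). Of its 19 measured genes, 0 passed limma over all probe sets and 9 adjusted over the list alone, against 5 and 11 without day 3 replicate 2, where the camera call also held with the estimated correlation (adjusted p 0.0272). The definitive endoderm list was higher with 19 of 23 genes above 0 (adjusted p = 0.00935, 0.788 with an estimated correlation, and 0.209 without day 1 replicate 3). The WNT signalling list was higher (adjusted p = 0.000206, 0.537 with an estimated correlation), with 0 of 28 genes past the test (2 without day 3 replicate 2) and 3 adjusted over the list alone (2 to 4). A range after a count gives its lowest and highest value leaving out 1 sample of the groups compared, or day 3 replicate 2. The FGF signalling list was higher (adjusted p = 0.00984, 0.633 with an estimated correlation, and 0.0681 without day 1 replicate 3). The amino acid and ER stress list was lower (adjusted p = 0.0196, 0.497 with an estimated correlation, and 0.109 without day 1 replicate 3), and its largest differences were -1.15 for the glutathione-degrading CHAC1 and -1.10 for the cystine transporter SLC7A11. The pluripotency list did not pass (adjusted p = 0.199), with 6 of 21 genes above 0. The extracellular matrix list passed only with day 3 replicate 2 left out (0.0566 with all samples, 0.0409 without, lower, and 0.827 without it with an estimated correlation). Its mean against day 0 was -0.93 in day 1 replicate 2 against -0.25 and 0.04 in the others.

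The DNA replication, HOX and hypoxia lists passed narrowly at day 1. DNA replication was higher (adjusted p = 0.0443, 0.633 with an estimated correlation) and lost its call without day 0 replicate 4 (0.306), day 1 replicate 1 (0.162) or day 1 replicate 3 (0.107). HOX genes were higher (0.0388, 0.466 with an estimated correlation) and lost it without day 0 replicates 1 (0.0757) or 2 (0.105) or day 1 replicates 1 (0.0826) or 3 (0.118). The hypoxia list was lower (0.0437, 0.474 with an estimated correlation), with the vasodilator peptide gene ADM at -1.37, and lost it without day 0 replicates 3 (0.0693) or 4 (0.0706), day 1 replicates 1 (0.0685) or 3 (0.0941), or day 3 replicate 2 (0.0605).

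Day 3 was compared with day 0 to ask which genes mark the passage from streak to endoderm. In day 3 replicates 1 and 3 SOX17 stood at 11.21 and 11.37 and in replicate 2 at 5.52, below the day 0 mean of 6.28 ± 0.51 (SD, n = 4). EOMES stood at 12.46 and 12.49 in replicates 1 and 3 and at 6.51 in replicate 2. With all 3 samples SOX17 differed from day 0 by 3.08 ± 1.08 (SE, adjusted p 0.366), EOMES by 3.87 ± 1.11 (adjusted p 0.256), MIXL1 by 3.61 ± 0.95 (adjusted p 0.205), GSC by 3.63 ± 1.09 (adjusted p 0.281) and GATA6, an endoderm GATA factor, by 4.25 ± 1.11 (adjusted p 0.201). Leaving out day 3 replicate 2, they rose by 5.00 (adjusted p 0.000231) for SOX17, 5.86 (0.000135) for EOMES, 5.17 (0.000529) for MIXL1, 5.54 (0.000231) for GSC and 5.95 (0.00167) for GATA6. The forkhead factor FOXA2 differed by 2.35, the chemokine receptor CXCR4 by 2.50 and the nodal antagonist CER1 by 1.88 with all samples, and rose by 2.99 (adjusted p 0.00621), 4.01 (0.0115) and 2.88 (0.00687) without that library. TBXT differed by -0.55 ± 0.58 (adjusted p 0.875).

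**Figure D1:**
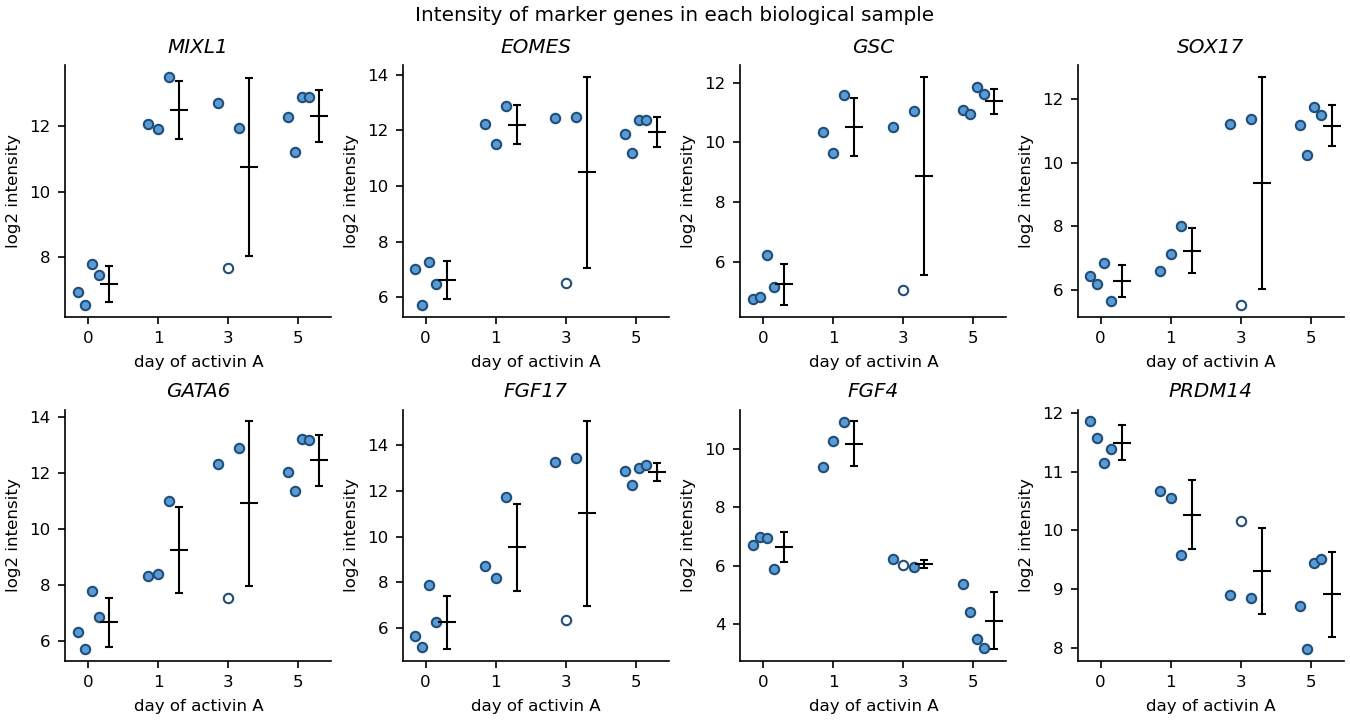
Log2 intensity of 8 genes (vertical axes) in each biological sample by day of activin A (horizontal axes). Points are samples, bars are the mean ± SD of the day, and the open point is day 3 replicate 2. MIXL1, EOMES and GSC were near their day 5 level at day 1, SOX17 only from day 3, and the open point lay near day 0 for MIXL1, EOMES, GSC and SOX17.

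The 5 genes past the test at day 3 (1 higher, 4 lower) were ones in which day 3 replicate 2 moved with the others. SLITRK2, a synaptic adhesion protein, rose by 2.91 ± 0.37 (adjusted p 0.0254, n = 3 and 4). LRRTM1, another synaptic protein, fell by 2.28 ± 0.33 (0.0443), SLC24A2 fell by 2.14 ± 0.27 (0.0254), the phospholipid flippase ATP10A fell by 2.02 ± 0.28 (0.0347) and the matrix protein THBS2 fell by 1.43 ± 0.20 (0.0347). In a fit of only the 2 groups compared 0 genes passed (0.217 to 0.362 for these 5). With the replicate number as a block only LRRTM1 of the 5 kept its call. Leaving out the dimmest probe sets removed some of the 5, SLC24A2 among them, and the 3 that stayed were called. All 5 calls were lost without day 0 replicate 1 (0.139 to 0.176), 2 (0.148 to 0.238) or 4 (0.0818 to 0.113) or day 3 replicate 1 (0.21 to 0.371) or 3 (0.171 to 0.305), each of which left 0 genes. Without day 0 replicate 3, LRRTM1 (0.137), SLC24A2 (0.0816) and THBS2 (0.137) lost theirs and 2 genes were left. Without day 3 replicate 2 the count was 590 (380 higher, 210 lower), with all 5 genes among them, and with all samples 1584 probe sets had an unadjusted p under 0.05.

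Among list genes at day 3, FGF17, a growth factor of the streak, differed by 4.76 ± 1.42 (adjusted p 0.28) and rose by 7.09 without day 3 replicate 2 (0.00102). PRDM1, a repressor active in early endoderm, differed by 3.59 ± 0.90 (0.192) and rose by 5.16 without it (0.000149). PRDM14, a regulator of the pluripotent state, differed by -2.18 ± 0.44 (0.161) and fell by 2.61 without it (0.00635). The WNT inhibitors DKK1 and NOTUM differed by 3.60 and 3.14 and rose by 4.98 (0.0012) and 4.08 (0.00551) without it.

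The definitive endoderm list was higher at day 3 (camera adjusted p = 1.18e-15, 0.295 with an estimated correlation), with 23 of 23 genes above 0, 0 past the test and 13 adjusted over the list alone (0 to 20), against 16 and 20 without day 3 replicate 2. Without that library its median rose from 1.98 to 3.06 and the call held with the estimated correlation (adjusted p 0.0272). The pluripotency list was lower (1.08e-08, 0.212 with an estimated correlation), with 0 of 21 genes lower over all probe sets (5 without day 3 replicate 2) and 9 adjusted over the list alone (3 to 13). The primitive streak list was higher (5.09e-05, 0.235 with an estimated correlation), with 0 of 19 higher (6 without day 3 replicate 2) and 5 adjusted over the list alone (0 to 7). The DNA replication list was lower (2.6e-06, 0.224 with an estimated correlation), with 7 of 21 lower adjusted over the list alone (0 to 6, and 1 without day 3 replicate 2), and the helicase genes MCM2 and MCM5 differed by -1.13 and -1.12. The cholesterol synthesis list was lower (0.000139, 0.218 with an estimated correlation), with 2 of 16 adjusted over the list alone (0 to 8, and 8 without day 3 replicate 2), and its genes SQLE and HMGCS1 differed by -1.26 and -1.02.

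Other list calls at day 3 hung on single samples. The WNT signalling list was higher (adjusted p = 0.00209, 0.633 with an estimated correlation) and lost its call without day 3 replicates 1 (0.13) or 3 (0.105). The later endoderm list was higher (0.0145, 0.218 with an estimated correlation), the glycolysis list lower (0.013, 0.633 with an estimated correlation) and the HOX list higher (0.0304, 0.444 with an estimated correlation). Those calls were lost without day 3 replicate 2 (0.12, 0.628 and 0.466), and that for HOX genes also without day 0 replicate 2 (0.0614). Further lists passed only without day 3 replicate 2, none with an estimated correlation (0.0605 or more). They were nodal and TGF-beta signalling (0.367 with all samples, 0.0262 without), BMP signalling (0.0873, 0.000435), mesenchymal and EMT (0.0713, 2.77e-05), extracellular matrix (0.422, 0.000206) and retinoic acid (0.186, 0.00654), all higher, and oxidative phosphorylation (0.455, 0.0127), lower.

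Day 5 was compared with day 0 to ask what sets the endoderm stage apart from stem cells. GSC rose by 6.12 ± 1.01 (SE, adjusted p 0.00353), to 11.37 ± 0.43 (SD, n = 4) from 5.25 ± 0.69 (n = 4). SOX17 rose by 4.88 ± 1.00 (0.012), FOXA2 by 3.00 ± 0.50 (0.00381), CXCR4 by 5.19 ± 0.94 (0.00598), GATA6 by 5.79 ± 1.03 (0.00554), EOMES by 5.33 ± 1.03 (0.00887) and MIXL1 by 5.17 ± 0.88 (0.00416). CER1 rose by 2.98 ± 0.62 (0.0131), and lost its call narrowly without day 0 replicate 1 (0.0513) or 2 (0.05). TBXT differed by -0.58 ± 0.54 (0.665).

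At day 5, 1009 probe sets were past the test, 474 higher and 535 lower, and 891 of them (446 higher, 445 lower) changed at least 2-fold. With 1 probe set per gene the number was 881. Over all probe sets, 2707 (14.6%) had groups that did not overlap, where chance separates 2.86%. The count of 1009 fell to 549 without day 0 replicate 1, 554 without day 0 replicate 2, 672 without day 0 replicate 4 and 639 without day 5 replicate 1. It reached 1614 without day 3 replicate 2, with all 1009 among them in the same direction.

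Among the genes that could be named, the largest rises at day 5 were of FGF17, by 6.56 ± 1.32 (adjusted p 0.0108), the neuropeptide gene GRP by 6.31 ± 0.72 (0.000611), GSC as above, DKK1 by 6.07 ± 0.83 (0.00112), DIO3, which inactivates thyroid hormone, by 5.87 ± 0.73 (0.000709) and the R-spondin receptor LGR5 by 5.80 ± 0.74 (0.000796). The day 0 means were low for GRP (3.30), DKK1 (3.71) and LGR5 (4.69), so the sizes and order of these rises depend on the pseudocount. The largest falls were of CNMD, a cartilage glycoprotein (fell by 4.24 ± 0.91, 0.0156), the cytokine receptor TNFRSF8 (fell by 3.48 ± 0.71, 0.0115, but fell by 2.51, 0.000845, without day 5 replicate 2), the secreted CYTL1 (fell by 3.21 ± 0.74, 0.0228) and the integrin adaptor FERMT1 (fell by 3.19 ± 0.38, 0.000666). CNMD lost its call without day 0 replicate 1 (0.0577) or 2 (0.0547), and CYTL1 without any 1 of day 0 replicates 1 to 4 or day 5 replicate 1 (0.0546 to 0.0716, where it fell by 2.62 without the last). The next were GUCA1A, an activator of guanylate cyclase (fell by 3.12, 0.0247), and the GABA transporter SLC6A11 (fell by 3.06, 0.0499). Their day 5 means of 1.69 and 2.08 were near the lowest values of the arrays, so the folds depend on the pseudocount (-1.16 and -1.28 with 16). GUCA1A lost its call without day 0 replicates 1, 2 or 4 (0.0711 to 0.0779) and fell by 2.40 without day 5 replicate 2. SLC6A11 lost its call without any day 0 sample or day 5 replicate 1 or 2 (0.0748 to 0.149) and in a fit of only the 2 groups compared (0.0762). It fell by 2.22 without day 5 replicate 1.

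The definitive endoderm list was higher at day 5 (camera adjusted p = 1.99e-22, 0.218 with an estimated correlation), with 17 of 23 genes higher (12 to 21), 0 lower and 21 higher adjusted over the list alone. Without day 3 replicate 2 the call held with the estimated correlation (0.0272). The pluripotency list was lower (1.77e-07, 0.218 with an estimated correlation), with 9 of 21 lower (3 to 11), 0 higher (0 to 1), and 12 lower (11 to 14) and 1 higher (0 to 1) adjusted over the list alone. PRDM14 fell by 2.58 ± 0.40 (adjusted p 0.00251) and the surface marker THY1 fell by 2.15 ± 0.25 (0.000653). The methyltransferase DNMT3B fell by 1.83 ± 0.43 (0.0242), a call lost without day 0 replicate 1 (0.0758), 2 (0.0712) or 4 (0.0654), without day 5 replicate 1 (0.0709) or in a fit of only the 2 groups compared (0.0574). The primitive streak list was higher (2.62e-05, 0.224 with an estimated correlation), with 7 of 19 higher (6 to 9) and 1 lower, and 10 (7 to 10) and 1 adjusted over the list alone.

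Genes of later endoderm derivatives were higher at day 5 (camera adjusted p = 0.0017, 0.207 with an estimated correlation), with 3 of 18 higher (3 to 4) and 5 adjusted over the list alone (3 to 6). The lipoprotein genes APOA2 and APOA1 rose by 4.78 ± 0.66 (adjusted p 0.0012) and 4.37 ± 0.36 (0.000174), and the T-box gene TBX3 by 2.74 ± 0.49 (0.00583). Of other lineages, 1 of 14 extraembryonic endoderm genes was higher (the vitamin B12 receptor CUBN, by 1.43 ± 0.23, adjusted p 0.00274) and 2 of 19 trophoblast genes (GATA3 by 2.06, 0.00611, and HAND1 by 2.05, 0.0486). GATA3 is also in the definitive endoderm list, and HAND1 is also the 1 mesoderm gene counted as higher below. HAND1 lost its call without any 1 of the 8 samples compared except day 5 replicate 2 (0.0826 to 0.147), and in a fit of only the 2 groups compared (0.0529). Of 16 mesoderm genes 1 was higher and 1 lower (the VEGF receptor KDR fell by 1.23, 0.0239, lost without any day 0 sample or day 5 replicate 1 or 2, 0.0504 to 0.0714). Of 23 neuroectoderm genes 1 was higher, the eye and pancreas factor PAX6, by 4.34 ± 0.43 (0.000332). Of 16 fibroblast genes 1 was higher (the proteoglycan LUM, by 4.57 ± 0.71, 0.00241, and by 3.88 without day 5 replicate 2) and 1 lower (THBS2, fell by 1.65 ± 0.19, 0.000545). Of 15 blood or endothelium genes 0 passed, but 2 were higher without day 3 replicate 2. Higher counts ran from 1 to 2 for the extraembryonic endoderm, trophoblast and neuroectoderm lists and from 0 to 3 for mesoderm. Lower counts ran from 0 to 1 for trophoblast and mesoderm and from 1 to 2 for fibroblast. Adjusted over the list alone the counts were 1 higher of the extraembryonic endoderm (1 to 2), 2 higher of the trophoblast (1 to 2, and 0 to 2 lower), 2 higher and 1 lower of the mesoderm (0 to 3 higher), 1 higher of the neuroectoderm (1 to 2, and 0 to 2 lower), 1 higher and 1 lower of the fibroblast (1 to 3 lower) and 0 of the blood or endothelium list (0 to 2).

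**Figure D2:**
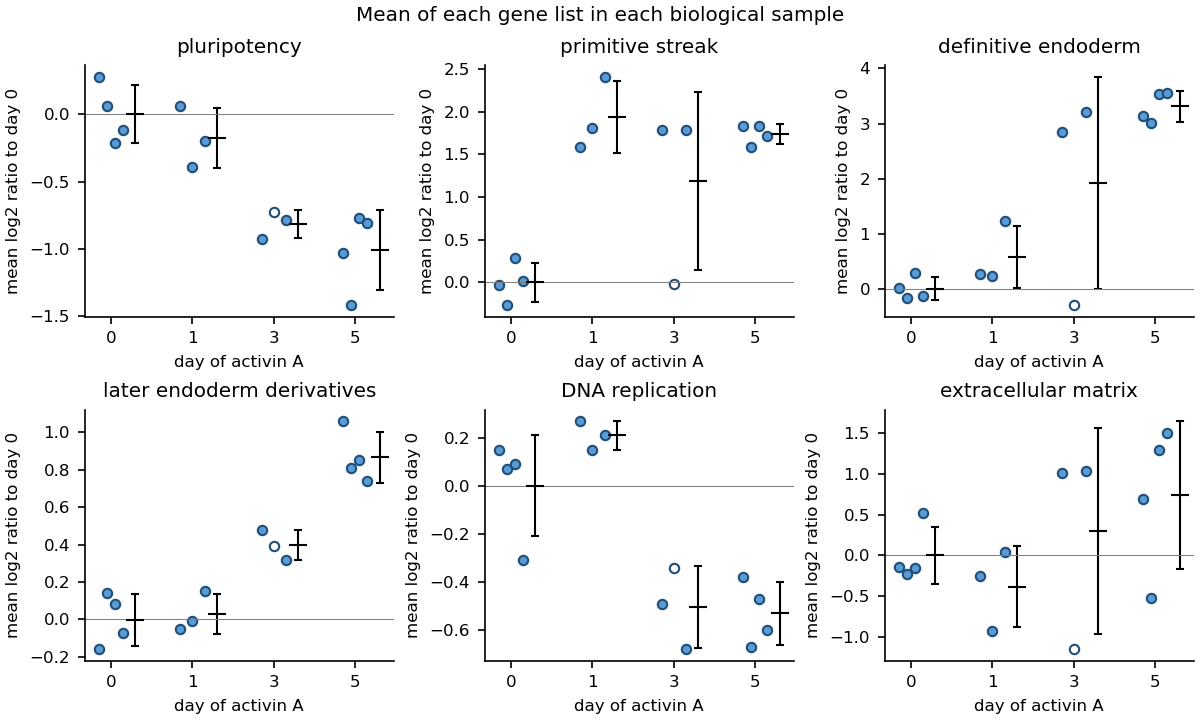
Mean log2 ratio to the day 0 mean over the measured genes of 6 lists (vertical axes) in each biological sample by day of activin A (horizontal axes). Points are samples, bars are the mean ± SD of the day, and the open point is day 3 replicate 2. The definitive endoderm mean was 2.85 and 3.21 in day 3 replicates 1 and 3, -0.30 in replicate 2 and 3.01 to 3.55 at day 5.

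The WNT signalling list was higher at day 5 (camera adjusted p = 7.38e-05, 0.499 with an estimated correlation), with 6 of 28 higher (4 to 9) and 1 lower, and 10 (7 to 13) and 1 (1 to 2) adjusted over the list alone. The secreted WNT inhibitor FRZB rose by 4.34 ± 0.56 (adjusted p 0.000802) and NOTUM by 3.35 ± 0.69 (0.0128). The BMP signalling list was higher (0.0111, 0.499 with an estimated correlation), with 5 of 19 higher on both counts (1 to 6 over all probe sets, 5 to 6 over the list alone), among them the BMP modulator BMPER (by 4.66 ± 0.55, 0.000664). Of 22 nodal and TGF-beta genes 5 were higher on both counts (4 to 5 over all probe sets, camera 0.0603, higher although the median was -0.12), among them the activin antagonist FST (by 2.83 ± 0.40, 0.00131), GDF3 (by 2.08 ± 0.36, 0.00441) and NODAL (by 1.27 ± 0.25, 0.0103). Of 19 FGF genes 3 were higher (2 to 4) and 5 lower (3 to 6), with 4 and 6 (6 to 7) when adjusted over the list alone (camera 0.483). The phosphatase DUSP4 rose by 2.59 ± 0.33 (0.0008) and FGF4 fell by 2.51 ± 0.46 (0.00681). Of 16 retinoic acid genes 1 was higher on both counts (1 to 2, and 1 to 4 over the list alone), the retinoic acid hydroxylase CYP26A1 (by 2.80 ± 0.55, 0.0095).

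Of 18 epithelial junction genes 3 were lower (1 to 4) and 0 higher (0 to 3) at day 5, and over the list alone 4 lower (2 to 6) and 2 higher (0 to 4) (camera adjusted p = 0.51), with E-cadherin, CDH1, down by 1.95 on the log2 scale (-1.95 ± 0.40, adjusted p 0.012). The mesenchymal and EMT list was higher (0.0243, 0.801 with an estimated correlation) with 0 of 20 genes past the test on both counts (0 to 1 higher and 0 to 1 lower). It lost its call without day 0 replicates 2 (0.0656) or 3 (0.0675) or day 5 replicates 1 (0.0536), 3 (0.0703) or 4 (0.259). The list mean was -0.52 in day 5 replicate 2, below -0.22 to 0.62 at day 0. In day 5 replicates 1, 3 and 4 it was 0.72, 0.81 and 1.18. The extracellular matrix list was higher (0.0243, 0.807 with an estimated correlation) with 2 of 22 higher on both counts (2 to 3), among them the cartilage collagen COL9A2 (by 1.77 ± 0.32, 0.00626). It lost its call without day 0 replicate 3 (0.0628) or day 5 replicates 3 (0.144) or 4 (0.309).

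The DNA replication list was lower at day 5 (camera adjusted p = 0.000247, 0.344 with an estimated correlation), with 4 of 21 lower (0 to 4) and 8 adjusted over the list alone (4 to 8). The origin recognition gene ORC1 fell by 1.11 ± 0.25 (adjusted p 0.0205), and lost its call without day 0 replicates 1, 2 or 3 or day 5 replicate 2 (0.0508 to 0.0785). The cell cycle G2/M list was lower (0.0174, 0.499 with an estimated correlation), with 1 of 22 lower (0 to 2) and 2 adjusted over the list alone (0 to 2), and lost its call without day 0 replicate 2 (0.0527) or day 5 replicate 4 (0.111). Of 21 cyclin and CDK inhibitor genes 3 were higher (2 to 3) and 1 lower (0 to 2), with 3 (3 to 4) and 4 (1 to 4) adjusted over the list alone. The CDK inhibitor CDKN1C rose by 2.11 ± 0.34 (0.00298) and the growth-arrest cyclin CCNG2 by 1.75 ± 0.26 (0.00155). Of 16 p53 and apoptosis genes 1 was higher (the autophagy gene TP53INP1, by 2.55 ± 0.27, 0.000459) and 1 lower (BCL2L11, fell by 1.33 ± 0.23, 0.00419) on both counts (1 to 2 over the list alone).

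The glycolysis list was lower at day 5 (camera adjusted p = 0.0267, 0.697 with an estimated correlation, and 0.176 without day 5 replicate 2), with 1 of 19 higher (0 to 1) and 2 lower (1 to 2), with 1 (0 to 2) and 4 (2 to 7) adjusted over the list alone, and the aldolase ALDOC fell by 1.53 ± 0.25 (adjusted p 0.00363). The hypoxia list was higher (0.0106, 0.295 with an estimated correlation), with 2 of 15 higher (1 to 3) and 3 adjusted over the list alone (2 to 4), and the mitophagy gene BNIP3 rose by 2.12 ± 0.30 (0.00129). Of 21 amino acid and ER stress genes 1 was higher (1 to 3) and 3 adjusted over the list alone (1 to 4). The 1 was the stress factor ATF3 (adjusted p 0.0147), at 10.17 ± 0.49 (SD) against 8.66 ± 0.37 at day 0. Of 16 cholesterol synthesis genes 0 passed on both counts (0 to 2 lower, and 0 to 3 lower over the list alone, camera 0.0595, and 0.0383 without day 3 replicate 2, lower, and 0.429 without it with an estimated correlation), and SQLE differed by -1.14 ± 0.32 (0.0595, and 0.0496 without day 3 replicate 2). None passed among 10 heat shock, 19 oxidative phosphorylation, 20 ribosomal protein and 9 motile cilia genes, over all probe sets or adjusted over the list alone. Of 13 HOX genes 0 passed on both counts, but without day 3 replicate 2 there were 2 higher over all probe sets and 3 adjusted over the list alone.

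Of 34 splicing regulators 2 were higher (2 to 3) and 1 lower (0 to 3) at day 5, with 3 (2 to 3) and 3 (0 to 3) adjusted over the list alone. RBM24 rose by 2.82 ± 0.54 (adjusted p 0.00879) and MBNL3 by 2.47 ± 0.41 (0.00365). Of 21 DNA methylation and Polycomb genes 1 was higher (0 to 2) and 1 lower (0 to 2), with 1 (1 to 2) and 2 (1 to 3) adjusted over the list alone, and the lower one was DNMT3B. Of 17 immediate early genes 1 was higher, the zinc finger factor KLF6, by 1.62 ± 0.32 (0.00937), and 1 lower on both counts (1 to 2 higher and 0 to 1 lower).

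**Figure D3:**
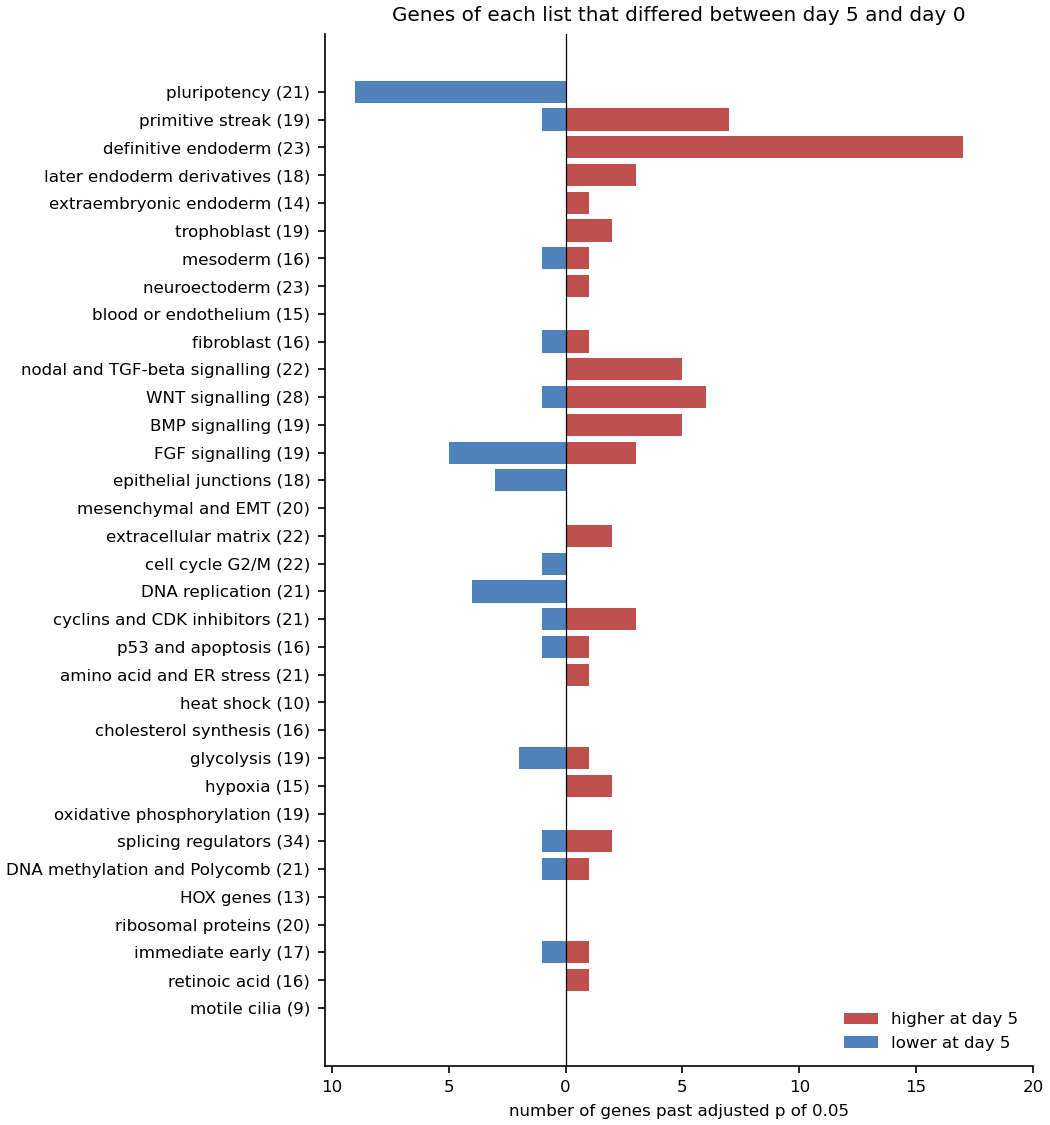
Number of genes of each of the 34 lists past an adjusted p of 0.05 between day 5 and day 0 (horizontal axis, higher to the right and lower to the left), with the number of measured genes in parentheses. The definitive endoderm list had 17 of 23 genes higher and the pluripotency list 9 of 21 lower.

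Day 3 was compared with day 1 to ask what follows the first response. FGF4 fell by 4.11 ± 0.53 (SE, adjusted p 0.0209), from 10.18 ± 0.77 (SD, n = 3) to 6.06 ± 0.14 (n = 3). EBF2, a helix-loop-helix factor, fell by 3.94 ± 0.54 (0.029, and fell by 3.34 without day 3 replicate 2), THBS2 fell by 2.39 ± 0.21 (0.000915), the cytokine subunit IL23A fell by 2.27 ± 0.32 (0.031) and the neural cell cycle inhibitor BRINP1 fell by 2.24 ± 0.29 (0.0209). The proteoglycan SDC2 rose by 1.96 ± 0.29 (0.0439). Those 6 genes (1 higher, 5 lower) were all that passed, and 1595 probe sets had an unadjusted p under 0.05. The count was 2 without day 1 replicate 1, 1 without day 1 replicate 2, day 3 replicate 1 or day 3 replicate 3, and 505 without day 3 replicate 2. THBS2 passed in each of these fits, but in a fit of only the 2 groups compared it reached 0.428 and the other 5 genes 0.428 to 0.757. FGF4 and BRINP1 reached 0.124 and 0.134 without day 3 replicate 1, EBF2 0.27, IL23A 0.278 and SDC2 0.278 without day 1 replicate 1.

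By lists, definitive endoderm genes were higher at day 3 than at day 1 (camera adjusted p = 1.77e-07, 0.549 with an estimated correlation), with 22 of 23 genes above 0. None of them passed limma, with or without adjustment over the list alone, against 10 and 18 without day 3 replicate 2. DNA replication genes were lower (4.23e-10, 0.207 with an estimated correlation), with 20 of 21 below 0, 0 past the test (0 to 1) and 8 adjusted over the list alone (1 to 11). Pluripotency genes were lower (1.77e-05, 0.235 with an estimated correlation) and hypoxia genes higher (0.00135, 0.218 with an estimated correlation). The primitive streak and FGF signalling lists were lower (0.00984 and 0.0191, 0.482 and 0.633 with an estimated correlation), and lost that call without day 3 replicate 2 (0.418 and 0.708) or day 1 replicate 3 (0.0772 and 0.0852).

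Smaller list calls between days 1 and 3 each hung on several samples. The mesenchymal and EMT list and the extracellular matrix list were higher (adjusted p = 0.0131 and 0.013, 0.788 and 0.801 with an estimated correlation), and lost their calls without day 1 replicate 2 (0.179 and 0.244) or day 3 replicates 1 (0.466 and 0.388) or 3 (0.16 and 0.389). The amino acid and ER stress list was higher (0.0127, 0.463 with an estimated correlation), and lost its call without day 1 replicate 3 (0.0512) or day 3 replicates 1 (0.182) or 3 (0.051). The cholesterol synthesis list was lower (0.029, 0.482 with an estimated correlation), and lost its call without day 1 replicates 2 (0.0795) or 3 (0.109) or day 3 replicates 1 (0.458) or 3 (0.0522). The splicing regulators list was lower (0.0421, 0.499 with an estimated correlation), and lost its call without day 1 replicates 1 (0.0874) or 3 (0.0725) or day 3 replicates 2 (0.342) or 3 (0.0524). The WNT signalling list did not pass and had opposite signs with all samples (adjusted p 0.876, lower) and without day 3 replicate 2 (0.0326, higher, and 0.651 with an estimated correlation). Other lists passed only without that library, none with an estimated correlation (0.0961 or more). They were BMP signalling (0.347 with all samples, 0.0042 without), retinoic acid (0.0778, 0.00298), epithelial junctions (0.422, 0.00894) and extraembryonic endoderm (0.0919, 0.0262), all higher, and oxidative phosphorylation (0.575, 0.0281), lower.

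Day 5 was compared with day 3 to ask what differs late. APOA1, the main protein of high density lipoprotein, rose by 3.94 ± 0.39 (SE, adjusted p 0.00293), to 11.01 ± 0.43 (SD, n = 4) from 7.07 ± 1.02 (n = 3), and kept its call without each of the 7 samples compared but not in a fit of only the 2 groups compared (0.339), where 0 genes passed. TMEM100, a BMP-dependent membrane protein, rose by 4.05 ± 0.61 (0.0268), the transporter partner CLTRN by 3.78 ± 0.50 (0.0158), the forkhead factor FOXQ1 by 3.66 ± 0.51 (0.0166, and by 3.02 without day 3 replicate 2, after means of 5.93, 8.51 and 6.23 at days 0, 1 and 3), the adhesion molecule VCAM1 by 3.31 ± 0.42 (0.0158) and the complement factor C5 by 2.63 ± 0.36 (0.0166). The kinase PRKG1 fell by 1.67 ± 0.28 (0.048). Without day 3 replicate 1 CLTRN, FOXQ1, VCAM1 and C5 reached 0.0995, TMEM100 0.148 and PRKG1 0.226. TMEM100 also lost its call without day 3 replicate 3 (0.103) or day 5 replicates 1 (0.0927) or 2 (0.0666), FOXQ1 without day 5 replicate 4 (0.0587), C5 without day 5 replicates 1 (0.0516) or 2 (0.0526), and PRKG1 without day 3 replicates 2 (0.0691) or 3 (0.119) or day 5 replicates 1 (0.134), 2 (0.0694) or 3 (0.104).

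In all 18 genes passed between days 3 and 5, 17 higher and 1 lower, and 1107 probe sets had an unadjusted p under 0.05. The count was 1 without day 3 replicate 1, 10 without day 3 replicate 3, day 5 replicate 1 or day 5 replicate 4, 7 without day 5 replicate 2 and 29 without day 3 replicate 2, and 11 of the 18 genes were shared with those 29. Cell cycle G2/M genes were lower, all 22 of them by value (camera adjusted p = 8.66e-06, 0.218 with an estimated correlation), with 0 past limma on both counts. The definitive endoderm list was higher (1.91e-11, 0.444 with an estimated correlation, and 0.108 without day 3 replicate 2).

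The nodal and TGF-beta signalling, WNT signalling, BMP signalling, extracellular matrix and hypoxia lists were also higher at day 5 than at day 3 (adjusted p = 0.0487, 0.014, 0.0328, 0.0187 and 0.0179, with 0.683, 0.667, 0.633, 0.807 and 0.344 with an estimated correlation). All 5 lost their calls without day 3 replicate 2 (0.898, 0.852, 0.708, 0.418 and 0.367), and the medians of the first 4 turned, from 0.20, 0.51, 0.22 and 0.36 to -0.05, -0.01, -0.11 and -0.57. They also lost them without day 5 replicate 4 (0.369, 0.088, 0.0681, 0.406 and 0.0801), and all but WNT without day 5 replicate 3 (0.157, 0.0627, 0.188 and 0.0664). The BMP signalling list lost its call without day 5 replicate 1 as well (0.0634). Lists that passed only without day 3 replicate 2, none with an estimated correlation (0.17 or more), were oxidative phosphorylation (0.295 with all samples, 0.00298 without), later endoderm derivatives (0.0565, 0.0141) and cholesterol synthesis (0.17, 0.0141), all higher. Epithelial junctions (0.669, 0.0216), glycolysis (0.593, 0.0301) and FGF signalling (0.422, 0.0387) were lower.

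Across the time course, 689 genes differed among the 4 time points by the moderated F test. Among them FGF4 (adjusted p 0.000768 in the F test) peaked at day 1 with a mean of 10.18 and ended at day 5 with 4.12, below its day 0 mean of 6.63. The count of 689 was 377, 346, 447 and 444 without day 0 replicates 1, 2, 3 and 4, 352 and 446 without day 1 replicates 1 and 3, 329 and 372 without day 5 replicates 1 and 3, and 1516 without day 3 replicate 2. Transient genes, higher at day 1 and lower again at day 5, numbered 0 by limma with all samples, and 50 simulations of unchanged groups gave at most 0. No group differed in those simulations, which set a count near 0 in advance. Without day 3 replicate 2 transient genes numbered 5, again with at most 0 in 50 simulations. Chosen after their values were seen, these 5 were FGF4, EBF2, IL23A, the WNT inhibitor APCDD1 and the T-box gene TBX22. Their day 1 means were 10.18, 9.01, 8.13, 8.91 and 8.55, and their day 0 means 6.63, 5.80, 6.11, 7.02 and 6.32.

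Genes called in the same direction were counted between days. SLC24A2 was the 1 gene shared by days 1 and 3 and the 1 shared by days 1 and 5. Leaving out the dimmest probe sets removed it before testing, and days 1 and 3 then shared 0 genes. All 5 day 3 genes were also called at day 5 in the same direction. In 50 simulations of unchanged groups the median was 0 shared, and at most 0, 2 and 0. No group differed in them, which set an overlap near 0 in advance, and a change on 1 day alone was not simulated. SLC24A2 fell by 2.24 ± 0.25 at day 5 (adjusted p 0.000551). The counts of 1 for days 1 and 3 and for days 1 and 5 were 0 without any 1 of the day 0 and day 1 samples or day 3 replicates 1 or 3. The former was also 0 without day 5 replicate 4, and the latter was 2 without day 5 replicate 2. The count of 5 was 0 without day 0 replicates 1, 2 or 4, day 1 replicate 3, day 3 replicates 1 or 3 or day 5 replicate 4. It was 1 without day 1 replicate 1 or day 5 replicate 3, 2 without day 0 replicate 3 or day 5 replicate 1, and 13 without day 5 replicate 2. Without day 3 replicate 2 the counts were 22, 29 and 464. There 1 gene, FGF4, was called in opposite directions at days 1 and 5. The 464 genes shared by days 3 and 5 split into 294 higher and 170 lower, where independent lists would share 15.47 and 9.78. With the day 0 samples split 2 against 2 between the comparisons, the medians of the splits were 4, 5.5 and 156 shared genes without day 3 replicate 2 and 0 with all samples.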

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

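The tests of explanations and the other splits of the samples were chosen after the results were seen.

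FGF4, THBS2, BRINP1 and PRKG1 lay above every day 0 sample in every day 1 sample and below every day 0 sample in every day 5 sample. FGF4 ran from 5.89 to 6.98 at day 0, 9.37 to 10.91 at day 1 and 3.20 to 5.38 at day 5. They were chosen for this order, which fixes the sign of the difference between day 5 and day 1, so no p value is given for it. It was -6.05 ± 0.50 for FGF4 (SE), -2.61 ± 0.20 for THBS2, -2.30 ± 0.27 for BRINP1 and -2.05 ± 0.28 for PRKG1.

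Some samples lay far from the other 3 of their group by Dixon's ratio, whose critical value for 4 samples is 0.829. Of 216 groups of 4 values tested, over genes considered for the text and sample measures, 13 were past it, where chance flags about 1 in 20 (10.8). Day 5 replicate 2 was lowest for TNFRSF8 (2.90 against 6.51 to 6.96, ratio 0.889), SQLE (9.67 against 10.91 to 11.09, 0.873) and GUCA1A (-0.46 against 2.31 to 2.57, 0.914). It also had the lowest median correlation with its group (0.858 against 0.935 to 0.939, ratio 0.951) and the highest mean over the dimmest 25% of probe sets (4.96 against 4.71 to 4.75, ratio 0.84). At day 0, replicate 3 was lowest for GUCA1A (0.878) and DNMT3B (0.846) and highest for LUM (0.882), replicate 1 was lowest for THY1 (0.872) and EBF2 (0.87), replicate 2 was lowest for ALB (0.917) and replicate 4 highest for SDC2 (0.881). At day 5, replicate 3 was highest for CDKN1C (0.898).

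On an index from 0 (day 0 mean) to 1 (day 5 mean) the median of the library labelled day 3 replicate 2 over 685 genes raised at day 5 was -0.11, against 0.74 and 0.88 in the other day 3 samples, with genes and means taken without day 5 replicate 2 and without any sample being measured. RNA or array quality of the kind seen in day 5 replicate 2 is argued against as the whole cause, since that library had 0.77, and so is a swap with a day 0 sample of this series, since the highest of them had 0.08. What stays open is that its cells may not have turned to endoderm, or that such a sample carries this label (-0.11), and an undifferentiated culture under this label, for which the values go both ways. The 5 day 3 genes lay past every day 0 sample in day 3 replicate 2 (THBS2 at 6.70 against 7.89 to 8.07, SLITRK2 at 8.74 against 5.68 to 6.83). They were called with it among the samples, which fixed this place, so they cannot count against such a culture. The pluripotency list was lowest of its day in day 1 and day 5 replicate 2 (-0.39 and -1.42). Their median deviations from the group mean for that list were -0.34 and -0.59. Day 3 replicate 2 had a mean of -0.73 for that list against -0.21 to 0.28 at day 0. A shift shared by the number 2 libraries could lower this mean, so it does not decide on such a culture. Larger sets do not decide either. The median of day 3 replicate 2 over 543 lowered genes was 0.25 (quartiles -0.21 and 0.69) against -0.07 to 0.18 at day 0 (SD 0.121). Subsets of 9, 33 and 62 genes deviated by at most 0.15, 0.25 and 0.35 in day 1 and day 5 replicate 2. There its median was 0.04, 0.39 and 0.41 (lower quartiles -0.14, 0.11 and 0.19), against up to 0.31, 0.23 and 0.22 at day 0. Over the 236 lower in neither of those libraries its median was -0.19. Those libraries deviate together with day 3 replicate 2, so this choice favours a low median and cannot count for such a culture. Of the 380 higher and 210 lower day 3 genes called without day 3 replicate 2, it lay past every day 0 sample in that direction in 104 and 107. It lay past them in the other direction in 164 and 50.

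The number 2 libraries of days 1, 3 and 5 deviated from their groups together, with correlations across genes of 0.671 to 0.745 between their deviations (genes are not independent replicates). Over probe sets with a mean log2 above 6, day 0 replicate 2 correlated with them at 0.36, 0.105 and 0.175. Day 0 replicate 3 did so at 0.351, 0.476 and 0.502, and day 0 replicates 1 and 4 were below 0. The pattern was thus not confined to number 2. Longer genes were lower in the number 2 libraries of days 1, 3 and 5, by a median of -0.39 in the longest 20% of genes and 0.20 in the shortest 20% for day 3 replicate 2. Removing each library's trend with gene span left the correlation between day 3 and day 5 replicate 2 at 0.739, which argues against gene length bias as the whole cause. RNA or array quality remains a candidate explanation, since ACTB and GAPDH were lowest of their day in replicate 2 in 6 of 6 cases. At day 0 both were lowest in replicate 3 (14.49 and 14.46). A shared culture or labelling run was not tested, because the labels give no batch.

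Other splits of the same samples were set beside each count, without regard to the replicate number. For day 3 against day 0 the real split was the only 1 of 35 with as many as 5 genes (highest other 0). For day 5 it was the only 1 of 35 with as many as 1009 (highest other 0). That share is the lowest that 35 splits allow. On these splits it argues against chance for day 5. For day 3 a fit of only the 2 groups compared left 0 genes, and the replicate number as a block left 1. Chance is therefore not called excluded for day 3. For day 1, 3 of 35 splits gave as many as 1 gene (highest other 1), so chance cannot be excluded. For day 3 against day 1, 2 of 10 splits gave 6 genes or more (highest other 12), and 10 splits are too few for a share under 0.05. For day 5 against day 3, 2 of 35 splits gave 18 genes or more. The other one called 8260 and set day 3 replicates 1 and 3 with day 5 replicates 3 and 4, which points to a structure of the samples, and chance cannot be excluded. For the F test, 4 of 100 splits gave 689 genes or more (highest other 3558). That share is under 0.05, but the highest split again points to a structure of the samples that can give such counts. Chance is therefore not called excluded for the F test. For transient genes the real count was 0, so all 100 of 100 splits had to give 0 or more (highest other 0), which tests nothing. Gene lists past camera were counted here with adjustment over the 34 lists of a contrast, which gave 5, 9 and 14 at days 1, 3 and 5, against 8, 9 and 12 over the 170 tests of the report. On that count 11 of 35 splits gave as many as the 5 of day 1 (highest other 8), 11 of 35 as many as the 9 of day 3 (highest other 14) and 2 of 35 as many as the 14 of day 5 (highest other 15), so chance cannot be excluded for these list counts.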

How the results depend on the processing

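Leaving out day 3 replicate 2 in contrasts that do not use it, and leaving out day 3 and day 5 replicate 2 together, were added after the results were seen. Counts by limma below are in the order day 1 against 0, day 3 against 0, day 5 against 0, day 3 against 1, day 5 against 3, F test, transient genes, and genes shared by days 1 and 3, 1 and 5, and 3 and 5. With all samples they were 1, 5, 1009, 6, 18, 689, 0, 1, 1 and 5. At an unadjusted p under 0.05 the first 5 were 1116, 1584, 3172, 1595 and 1107. Where counts moved, the cause was not tested. Signal over background limits these arrays, and faint genes compress toward the floor.

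With all 16 arrays and the sample as a random block the counts were 14, 8, 990, 8, 20, 729, 3, 1, 6 and 8. Technical replicate 2 alone gave 1, 3, 1055, 5, 18, 688, 0, 1, 1 and 3. Fits of only the 2 groups compared gave 20, 0, 1024 (542 higher, 482 lower), 0 and 0. Without the dimmest 25% of probe sets the counts were 12, 7, 1126, 8, 25, 799, 3, 0, 5 and 7. A variance trend with robust eBayes gave 12, 1, 1042, 7, 18, 745, 3, 0, 4 and 1. At an adjusted p under 0.01 they were 0, 0, 412 (227 higher, 185 lower), 1, 1, 216, 0, 0, 0 and 0, and with a pseudocount of 16 they were 17, 8, 1155, 8, 29, 807, 3, 1, 9 and 8. Quantile normalization and median centring moved none of these counts by more than 1.5 times. The deposited values already look quantile normalized, so these alternatives could hardly move them and do not test the normalization. With 1 probe set per gene, which leaves out those with several symbols or none, the counts were 1, 5, 881, 7, 13, 601, 0, 1, 1 and 5. With the day 0 samples split 2 against 2 the shared counts had a median of 0, 0 and 0.

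Array weights gave 2543, 2800, 3000, 6302, 798, 8421, 135, 545, 621 and 1581. Their estimate did not converge, with weights from 0.0972 (day 3 replicate 2) to 17.3 (day 1 replicate 1), so these counts are not relied on. Leaving out day 3 and day 5 replicate 2 together gave 122, 1057, 1835, 1179, 18, 2128, 9, 51, 61 and 756. Leaving out 1 sample at a time, the first 7 counts ran from 0 to 46, 0 to 590, 549 to 1614, 1 to 505, 1 to 29, 329 to 1516 and 0 to 5, and the shared counts from 0 to 22, 0 to 29 and 0 to 464, highest without day 3 replicate 2. Some calls at days 1 and 3 also moved without a sample of a group not compared, through the shared estimate of spread.

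With the replicate number as a replicate block the counts were 0, 1, 1448, 1, 21, 859, 0, 0, 0 and 1, 990 of the 1448 were shared with the 1009, and of the 5 day 3 genes 1 was shared, LRRTM1 (adjusted p 0.0483). The numbers do not pair the samples by the labels. Of 19 pairs with the same number 13 correlated over 0.1 (-0.431 to 0.741), and 9 of 14 samples correlated best with their own number, a hint from the data and not the design.

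Of 170 list tests 47 passed with camera at the preset correlation (30 up, 17 down), 0 with the estimated correlation, 16 with fry (7 up, 9 down), and 38 to 54 leaving out 1 sample. Directions as camera gives them, not those of the medians, turned for WNT signalling between days 1 and 3 (adjusted p 0.876 with all samples, 0.0338 with array weights, 0.0318 without both number 2 libraries, 0.0326 to 0.845 leaving out 1 sample). They also turned between days 3 and 5 for WNT signalling (0.014, and 0.000136 to 0.852 leaving out 1 sample) and extracellular matrix (0.0187, and 2.89e-06 to 0.418). The turns left out day 3 replicate 2 or weighted it least. They count only lists that passed in at least 1 of the 2 fits compared. A further 194 of 2788 alternative results had the other sign and passed in neither fit.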

Other observations

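The genes and list deviations in this part were chosen after their values were seen, and none was tested.

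The fetal liver gene AFP, the hepatocyte gene ALB and the transport protein gene TTR stayed near their day 0 levels at day 5. AFP ran from 5.05 to 6.48 at day 5 and 5.46 to 6.24 at day 0, ALB from 4.14 to 5.45 and 4.29 to 4.53, and TTR from 5.83 to 6.30 and 4.79 to 6.51.

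Of the 34 lists, the 22 extracellular matrix genes deviated lowest from their group mean in day 1 and day 5 replicate 2 (medians -0.62 and -1.57), and second lowest in day 3 replicate 2 (-1.39), after definitive endoderm (-2.40). The 19 oxidative phosphorylation genes deviated highest in all 3 (0.44, 0.69 and 0.74).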
